A study of Mus musculus with 12 samples.

How the data were processed

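Liver samples of germ-free male mice were profiled by total RNA sequencing, 6 after PBS and 6 after GH injections. Per the labels' protocols, libraries were made from 250 ng of total RNA with a stranded kit after depletion of ribosomal RNA, amplified for 12 cycles, pooled by 24 and sequenced from both ends for 125 cycles. STAR 2.4.0i and the mm10 assembly are named in the submitters' processing notes. The program that counted reads, its annotation, its use of strand and its treatment of reads with several matches are not given in the sources used here. The authors deposited 1 table of raw counts of exonic reads per gene for the 12 libraries, without normalization: 38087 genes under Ensembl identifiers with older symbols, of which 10628 had no count in any library. No mitochondrial gene is in the table. Identifiers were matched to GENCODE M21 (36308 found), which also gave coordinates. There were 278 symbols that stand on more than 1 identifier, and 101 genes with a total of at least 20 had counts identical to another gene. The labels name 50 µg of GH per mouse, and whether this is per injection or per day is not given in the sources used here.

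How these counts were made could affect the measurements. In 10 pairs of genes on opposite strands, with the smaller inside the larger gene's span, the count density of the inner gene was a median of 0.0345 of that of the outer one, and in 4 pairs on the same strand it was 1.34, with a range of 0.169 to 3.11. Opposite strands thus looked separated. Whether genes on the same strand share reads in general is not settled by so few pairs. Serpina3m and Serpina3k, which overlap on the same strand, had near-equal CPM in every library and so look to share reads. Overlaps on the same strand by at least 50 exonic bases are named beside the genes. Saa, Ugt2b, Cyp2c, Cyp4a, Mup, Serpina3 and Slc22a genes have near-identical copies among which reads may have been split or lost.

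Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr (minimum count 10), which left 14235, and libraries were scaled by TMM. The comparison of GH with PBS used all 12 libraries, a robust quasi-likelihood fit with the group as the only term, a two-sided F test, Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.168. CPM are counts-per-million after TMM scaling, and log2 fold changes are GH minus PBS. SE were derived from the F test, as the absolute log2 fold change divided by the square root of the F statistic. An "adjusted p" of a gene is from this edgeR test unless another tool is named.

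For gene lists, limma 3.58.1's camera was run with its preset inter-gene correlation of 0.01 and again with a correlation estimated per list, which gives the adjusted p quoted "with an estimated correlation". Its fry function gave a test of movement one way and a mixed test of change in either direction. Adjustment was over the 20 process lists together and over the 8 cell type lists with at least 2 measured members. Of the process lists 12 passed with the preset correlation, 0 with an estimated one (lowest adjusted p 0.0614) and 6 with fry's test of movement one way. By fry these were male-biased (adjusted p = 0.00302), female-biased (0.0172), xenobiotic metabolism (0.00492) and acute phase (0.0172). The others were interferon response (0.0221) and immediate-early and heat shock (0.00302). Of the cell type lists 1 passed with the preset correlation, 0 with an estimated one and 0 with fry's test of movement one way. Only stellate cell and fibroblast (adjusted p = 0.00028) and sinusoidal endothelium (0.0424) passed fry's mixed test among the cell type lists. The gene-wise test, camera with its preset correlation, the sex index, these gene lists, the rule for named genes and the alternatives, except for the 1 named as added, were fixed before the data were examined. The estimated correlation and fry's test of movement one way were among these alternatives. Its mixed test and an exact permutation test of each list's mean log2 CPM per library were not in that design. By the latter 7 of the process lists passed (male-biased, female-biased, GH and STAT5 signalling, cholesterol synthesis, xenobiotic metabolism, acute phase, and immediate-early and heat shock) and 0 of the cell type lists. Tests of the closing section were chosen after the main results were seen, except for the splits of the libraries and the fits with 1 library left out.

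The process lists were male-biased, female-biased, GH and STAT5 signalling, major urinary proteins, circadian clock, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation and PPARA targets, bile acid synthesis and transport, gluconeogenesis and insulin response, xenobiotic metabolism, acute phase, interferon response, cell cycle, immediate-early and heat shock, ER stress and integrated stress response, amino acid and urea metabolism, pericentral hepatocyte, periportal hepatocyte and cytosolic ribosomal proteins. The cell type lists were Kupffer cell and macrophage, sinusoidal endothelium, stellate cell and fibroblast, cholangiocyte, B cell, T and NK cell, neutrophil, erythroid cell, pancreas, adipose tissue and muscle. Of 622 list genes 620 were found in the table, and 11 genes stand in more than 1 list. The sex index used log2 CPM with a prior count of 0.5 and an exact permutation test of the difference of means.

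The genes named were Igf1, Igfals, Socs2, Cish, Ghr, Bcl6 and Stat5b whatever their result, the 10 higher and 10 lower genes of largest absolute change among those past the threshold with a mean of at least 1 CPM, all 6 GH libraries on the same side of the PBS mean and a symbol that is not a predicted model or pseudogene, and up to 4 members of smallest p per list. Hsd3b5, Slco1a1, Egfr, Cyp2c40, Cyp2b9, Mup2, Creb3l3, Vnn1, Por, Alas1, Orm3, Sdf2l1, Cxcl9 and the complement and coagulation genes of the closing section were named after their values were seen.

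The procedure was tested on simulated counts for the same 14235 genes and 12 libraries, with 200 genes changed. It recovered 50.7% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 98.5% of those changed 4-fold. Of its 162 calls 4.32% were false, and it made 0 calls with no gene changed. With no list changed, camera called 1 of 27 lists. Genes were simulated independently of each other, so this does not show how camera performs on lists of correlated members. In the data the estimated correlation was 0.446 for the male-biased list and 0.823 for the ribosomal protein list.

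Alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, the replicate number as a block, 1 surrogate variable (sva 3.50.0), non-robust estimation, other thresholds, families left out of the sex-biased lists, and each library left out in turn. The fit without GH replicate 6 and PBS replicate 5 together was chosen after seeing the data. All 12 libraries of the table entered the comparison. Reads, splicing and intronic signal were not analysed here.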

Results

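RNA was sequenced from the livers of male C57BL/6j mice that were germ-free, that is, raised without any microorganisms. The mice were 13 to 16 weeks old. One group received recombinant human growth hormone (GH, 50 µg per mouse) under the skin and the other received phosphate-buffered saline (PBS), with 2 injections a day at ZT 2 and ZT 14 for 5 days. ZT is the number of hours after lights on, and the livers were taken at ZT 2. GH is a pituitary hormone that acts on the liver through the GH receptor, the kinase JAK2 and the transcription factor STAT5B. Male rodents secrete it in separated pulses and females more evenly, a difference that sets much of the sex-biased expression of the liver. Human GH also binds the prolactin receptor.

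The data were 12 libraries of ribosomal RNA-depleted total RNA, 6 per group, with values given as counts of exonic reads per gene. Totals ran from 19523104 to 23278931 counts per library, with a mean of 21.2 ± 1.45 M in PBS and 21.4 ± 1.29 M in GH (SD, n = 6; M, mega). The labels number the samples within each group without stating further how they were drawn, so p-values measure the spread between these samples. No pair of libraries within a group matched to within counting noise, with chi-square per degree of freedom from 8.95 to 75.9. Albumin (Alb) took 7.63 ± 0.598% of the counts in PBS and 6.11 ± 0.620% in GH (SD, n = 6; two-sided exact permutation p = 0.00433, 0.0217 after adjustment over 5 such measures). The share of the 20 most abundant genes, 26.8 ± 0.867% in PBS, did not pass the same test (adjusted exact p = 0.0505).

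The comparison of GH with PBS addresses how injected GH changes liver expression in male mice that have no microbiota. Of 26 genes known to be higher in male than in female liver 12 rose in the GH livers (list adjusted p = 0.0614 with an estimated correlation), among them Cyp7b1, a steroid hydroxylase, from 206 ± 73.5 to 655 ± 99.1 counts-per-million (CPM; SD, n = 6). Of 24 female-biased genes 6 fell and 18 did not pass (list adjusted p = 0.129 with an estimated correlation), and the prolactin receptor gene Prlr went from 112 ± 26.7 to 36.3 ± 7.85 CPM. Of 21 genes of GH and STAT5 signalling 2 rose, 5 fell and 14 did not pass (list adjusted p = 0.330; 0.468 with an estimated correlation). Among the 5, Socs2, a feedback inhibitor of GH signalling, went from 13.8 ± 7.51 to 1.32 ± 0.284 CPM, and Igf1, the main mediator of GH on growth, from 493 ± 51.6 to 310 ± 60.6 CPM. Of 27 acute phase genes 8 rose and 1 fell (list adjusted p = 0.129 with an estimated correlation), and the serum amyloid P gene Apcs went from 102 ± 23.1 to 284 ± 58.7 CPM. Fry's test of movement one way passed for the male-biased, female-biased and acute phase lists (adjusted p = 0.00302, 0.0172 and 0.0172). It did not pass for GH and STAT5 signalling (adjusted p = 0.185). Some genes of cholesterol synthesis, drug metabolism and the interferon response fell. All directions are those of the labels.

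Of 14235 genes tested with edgeR's quasi-likelihood test, 682 changed at a Benjamini-Hochberg adjusted p under 0.05, 323 of them higher and 359 lower in GH, and 2702 genes had an unadjusted p under 0.05. Most changes were moderate: the median absolute log2 fold change of the changed genes was 0.48, with 62 genes at least 2-fold higher and 59 at least 2-fold lower. In 452 of the 14235 tested genes (3.18%) the 6 GH values and the 6 PBS values did not overlap, against 0.216% by chance, and 373 of these genes were among the changed. The count fell to 447 without GH replicate 1 and to 434 without GH replicate 2, while 1022 genes were called without GH replicate 6 and PBS replicate 5, the libraries farthest from their groups on principal components 2 and 3. Higher genes made up 47.4% of the calls, against 24.3% when libraries were scaled by their totals alone, a scaling that moved the median of all genes by -0.06 on the log2 scale.

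Among the largest increases, all relative to PBS, A2m (alpha-2-macroglobulin, a plasma protease inhibitor) rose by 5.24 ± 0.37 on the log2 scale (SE, n = 6; adjusted p = 6.98e-06), from 0.213 ± 0.176 to 7.87 ± 2.17 CPM. Saa2 rose by 5.07 and Saa1 by 3.88, but GH replicate 6 was far above the rest, and without it the values were 3.66 and 3.27; DESeq2 gave Saa2 no adjusted p. Ugt2b38 (3.96) and Ugt2b37 (2.97), genes of the glucuronosyltransferase family, rose with the carboxylesterase gene Ces4a (3.67). The serpin gene Serpina5 rose by 2.75, the male-biased proteoglycan gene Cspg5 by 2.64, Nucb2, which encodes the precursor of nesfatin, by 2.18 and the glutamate receptor gene Gria3 by 2.15. All 6 GH libraries lay above the PBS mean for each of these 10 genes. Saa, Ugt2b, Cyp2c, Cyp4a, Mup and Serpina3 genes have near-identical relatives, so counts within these families are uncertain, and Gria3 overlaps AL672290.1.

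Among the genes lower in the libraries labelled GH, Cyp4a14, a fatty acid hydroxylase gene, changed by -5.07 ± 1.09 (SE, n = 6; adjusted p = 0.0271), from 150 ± 185 to 4.50 ± 3.47 CPM; without PBS replicate 1 it was -4.39, and the adjusted p passed 0.05 in 5 of the 12 fits with 1 library left out (highest 0.0653, without GH replicate 2). Cish changed by -3.64, or -2.99 without PBS replicate 4. Onecut1, which encodes the liver transcription factor HNF6 and overlaps Gm20649, changed by -3.61, and Socs2 by -3.38. The magnesium transporter-like gene Nipal1 (-2.83), the cytochrome gene Cyp2c38 (-2.71), Serpina7, which encodes thyroxine-binding globulin (-2.52), the peroxisomal transporter gene Abcd2 (-2.12) and the glutathione transferase gene Gstt3, which overlaps Gm20441 (-2.07), fell as well. A signal recognition particle RNA gene, Metazoa_SRP_ENSMUSG00000093220, changed by -2.91. For each of these 10 genes all 6 GH libraries lay below the PBS mean. Gria3 and the signal recognition particle gene lost their calls in 4 and 3 of the 12 fits with 1 library left out (highest adjusted p 0.0607 and 0.0586).

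**Figure D1:**
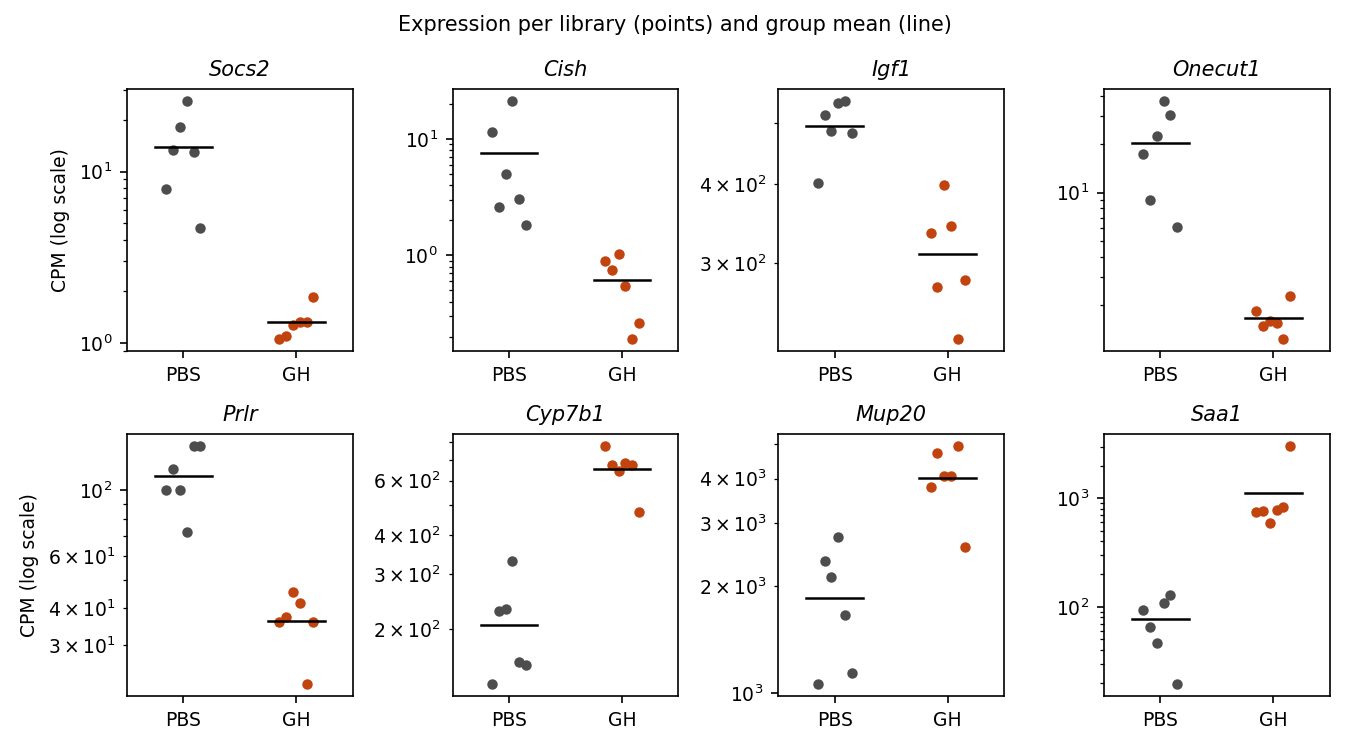
CPM (log axis) of 8 genes in each of the 6 PBS and 6 GH libraries (points, in replicate order) with the group means (lines). Socs2, Cish, Igf1, Onecut1 and Prlr were lower and Cyp7b1, Mup20 and Saa1 higher in GH, and GH replicate 6 had 3056 CPM of Saa1 against 591 to 828 in the other GH libraries.

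The list of GH and STAT5 signalling genes, fixed like the other lists before the data were examined, held changes both ways: of 21 measured members 2 rose and 5 fell (5 and 6 adjusted over the list alone). Its median log2 fold change was 0.01, its mean was -0.37, and the camera test gave a downward direction that did not pass (adjusted p = 0.330; 0.468 with an estimated correlation). The mean log2 CPM of the list per library, a measure in which Socs2, Cish and Onecut1 weigh heavily, was lower in every GH library than in every PBS library (difference -0.32, exact permutation p = 0.00216, adjusted 0.0144). With 1 library left out the median ran from -0.04 (GH replicate 6) to 0.03 (GH replicate 5), and without PBS replicate 6 the camera test passed (adjusted p = 0.0446). A test for change in either direction passed (fry mixed adjusted p = 6.07e-08). It does not set this list apart, since most process lists passed it, interferon response with a smaller value (9.00e-09). Those that did not were circadian clock, fatty acid synthesis, cell cycle, amino acid and urea metabolism, and cytosolic ribosomal proteins. Socs2 (chromosome 10, 95385362 to 95417180) fell by 3.38 ± 0.40 on the log2 scale (SE, n = 6; adjusted p = 0.00084), and its values in the groups did not overlap. Cish, another feedback inhibitor (chromosome 9, 107296026 to 107302784), went from 7.53 ± 7.56 to 0.610 ± 0.337 CPM (adjusted p = 0.0201). Igf1 (chromosome 10, 87858265 to 87937042) changed by -0.67 ± 0.12 (adjusted p = 0.00381) and Igfals, which encodes the labile subunit that carries IGF1 in plasma (chromosome 17, 24865997 to 24882010), by -0.69 ± 0.17 (adjusted p = 0.0323). The Igfals call was lost in 7 of the 12 fits with 1 library left out (highest adjusted p 0.0670, without PBS replicate 3).

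The 2 members that rose were Serpina3k, which overlaps Serpina3m, from 13874 ± 2653 to 24219 ± 2348 CPM, and Serpina3c, by 1.84 (adjusted p = 0.00182). Bcl6 encodes a repressor of female-biased genes and had 26.1 ± 19.7 CPM in PBS and 67.1 ± 11.6 in GH (log2 fold change 1.36, adjusted p = 0.151). The GH receptor gene Ghr had a log2 fold change of 0.23 (adjusted p = 0.134), and Stat5b one of 0.01 (adjusted p = 0.976). Coordinates are those of the mm10 assembly in the GENCODE M21 annotation and span the whole gene, introns included.

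In the male-biased list, of 26 measured members 12 rose and none fell in edgeR (18 and 1 in DESeq2; 21 and 1 adjusted over the list alone), with a median log2 fold change of 0.99 (camera adjusted p = 1.14e-25; adjusted p = 0.0614 with an estimated correlation). C8b and C8a, which encode chains of complement component C8, rose by 0.96 ± 0.12 and 0.82 ± 0.12 (SE, n = 6; adjusted p = 0.000227 and 0.000924). Cyp7b1 (chromosome 3, 18071950 to 18243338) rose by 1.67 ± 0.21, and Cspg5 and Ugt2b38 were also among the 12. The response was not shared by all members: Hsd3b5, Slco1a1 and Egfr had log2 fold changes of 0.18, 0.19 and -0.76, with adjusted p of 0.818, 0.782 and 0.0855. Hsd3b5 and Slco1a1 ran from 0.04 (without PBS replicate 1) and 0.05 (without PBS replicate 5) to 0.34 each without GH replicate 6. Egfr was the 1 lower gene when p was adjusted over the list alone, and without PBS replicate 1 it passed over all genes (adjusted p = 0.0220).

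In the female-biased list, of 24 measured members none rose and 6 fell in edgeR (1 and 13 adjusted over the list alone), with a median of -0.90, or -1.49 without GH replicate 6 (camera adjusted p = 9.66e-10; adjusted p = 0.129 with an estimated correlation). Prlr (chromosome 15, 10177238 to 10349180, overlapping RP23-74N15.4) changed by -1.62 ± 0.19 (SE, n = 6; adjusted p = 0.000676), and Trim24, a transcriptional cofactor gene, by -0.62 ± 0.12 (adjusted p = 0.00783). The organic anion transporter genes Slc22a26 and Slc22a27 changed by -1.30 and -1.50, and the other 2 were Abcd2 and Cyp4a14. Some members went the other way or did not pass: Cyp2c40, higher when p was adjusted over the list alone, had a log2 fold change of 1.67 (adjusted p = 0.166) and Cyp2b9 one of -4.60 (adjusted p = 0.0622). Cyp2c40 passed without PBS replicate 6 (adjusted p = 0.0329), and Cyp2b9 passed without PBS replicate 2 or PBS replicate 4 (adjusted p = 0.0420 and 0.0483). With multigene families left out, 17 male-biased and 15 female-biased members had medians of 1.16 and -0.79.

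A sex index per library, the mean log2 CPM of the male-biased genes minus that of the female-biased genes, was 3.82 ± 1.17 in PBS and 6.07 ± 0.738 in GH (SD, n = 6), a difference of 2.25 (two-sided exact permutation p = 0.00649 over 924 assignments, of which the smallest possible is 0.00216). The index of GH replicate 6 was 4.58, inside the PBS range of 2.20 to 5.14, while the other 5 GH libraries lay between 6.25 and 6.52.

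**Figure D2:**
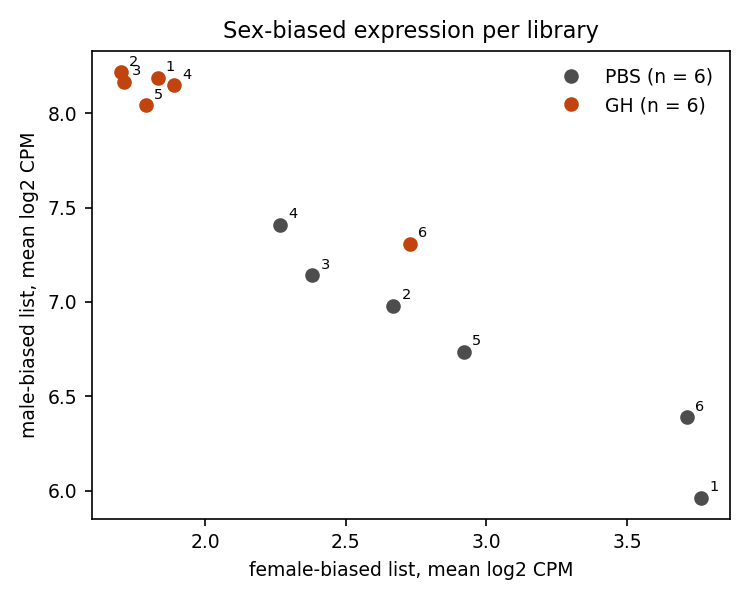
Mean log2 CPM of the 26 male-biased genes against that of the 24 female-biased genes, 1 point per library, numbered by replicate, for PBS and GH (n = 6 each). Replicates 1 to 5 of GH form a tight group at high male-biased and low female-biased expression, and GH replicate 6 lies among the PBS libraries.

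The major urinary proteins, pheromone carriers made in male liver, had 15 measured members, of which 2 rose and none fell in edgeR (2 and 1 adjusted over the list alone; the 1 was Mup2, with a log2 fold change of -0.84 and an adjusted p of 0.109 over all genes, 0.0319 without GH replicate 6 and 0.0406 in DESeq2). Their median was 0.35 (camera adjusted p = 0.0327; adjusted p = 0.643 with an estimated correlation), and the list lost its call in 7 of the 12 fits with 1 library left out. The median was 0.15 without PBS replicate 5, 0.20 without GH replicate 5 and 0.64 without PBS replicate 4. Mup20 (darcin) rose from 1846 ± 679 to 4028 ± 840 CPM (adjusted p = 0.0236) and Mup21 from 269 ± 135 to 739 ± 173 (adjusted p = 0.0323). Mup20 lost its call in 2 of those fits and Mup21 in 9 (highest adjusted p 0.0530 and 0.0709).

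Of 25 measured genes of cholesterol synthesis none rose and 2 fell in edgeR (0 and 4 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 4.9e-10; adjusted p = 0.283 with an estimated correlation). Hsd17b7 changed by -0.84 ± 0.17 (SE, n = 6; adjusted p = 0.0158) and Idi1, isopentenyl diphosphate isomerase, by -1.13 ± 0.27 (adjusted p = 0.0360), the latter losing its call in 9 of 12 fits with 1 library left out (highest adjusted p 0.0807). Srebf2, the transcriptional regulator of the pathway, had a log2 fold change of -0.41 (adjusted p = 0.0810) and Stard4 one of -0.60 (adjusted p = 0.0875), and they passed without PBS replicate 4 (0.0175) and without GH replicate 6 (0.0301), and in DESeq2 (0.0419 and 0.0127). None of the 22 fatty acid synthesis genes passed in edgeR (0 adjusted over the list alone). Their median was -0.27 (camera adjusted p = 0.0333; adjusted p = 0.611 with an estimated correlation), or -0.15 without PBS replicate 4 (adjusted p = 0.133) and -0.17 without GH replicate 6 (adjusted p = 0.221). The list lost its call in 6 of the 12 such fits, and its member with the smallest p was Fads2, a desaturase gene, at -0.39 (adjusted p = 0.0666; 0.0422 without PBS replicate 3, 0.0451 without GH replicate 3 and 0.0264 in DESeq2).

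Of 28 measured genes of fatty acid oxidation and targets of the receptor PPARA none rose and 5 fell in edgeR (1 and 9 adjusted over the list alone; the 1 was Creb3l3), with a median of -0.13, or -0.05 without PBS replicate 6 (camera adjusted p = 0.00105; adjusted p = 0.468 with an estimated correlation). The 5 were the peroxisomal enzyme genes Acaa1b (-0.68 ± 0.11) and Ehhadh (-0.53 ± 0.11), the acyl-CoA thioesterase genes Acot1 (-1.21) and Acot2 (-0.87), and Vnn1 (-1.90). Calls of Acot1, Acot2 and Vnn1 were lost in 4, 6 and 7 of the 12 fits with 1 library left out (highest adjusted p 0.0630, 0.0723 and 0.0743). The 20 measured bile acid genes showed no shift one way (median -0.05, or -0.09 without PBS replicate 5 and -0.02 without PBS replicate 6, camera adjusted p = 0.351). Fry's mixed test of change in either direction passed (adjusted p = 2.02e-06). Amacr, which acts in side chain oxidation, rose by 0.43 ± 0.06 (adjusted p = 0.000676), and Akr1d1, a steroid 5-beta-reductase gene, changed by -0.40 ± 0.08 (adjusted p = 0.00626). Cyp7a1, the rate-limiting enzyme of the classical pathway, changed by -1.80 ± 0.44 (adjusted p = 0.0446), a call that was lost in 10 of the 12 fits (highest adjusted p 0.101). With p adjusted over the list alone 1 bile acid gene was higher and 3 were lower.

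Xenobiotic metabolism genes, which encode enzymes that modify drugs and foreign compounds, had 34 measured members, of which 1 rose and 9 fell (1 and 15 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 1.39e-08; adjusted p = 0.0998 with an estimated correlation). Gstt1, a glutathione transferase gene, changed by -0.99 ± 0.09 on the log2 scale (SE, n = 6; adjusted p = 1.23e-05), and Cyp2c29, which overlaps Cyp2c53-ps, went from 1721 ± 356 to 751 ± 154 CPM (SD; adjusted p = 0.000818). The sulfotransferase gene Sult1a1 changed by -0.82 ± 0.15. Por, the reductase that feeds electrons to the cytochromes P450, changed by -1.40 and Alas1, the rate-limiting enzyme of haem synthesis in liver, by -1.93 (adjusted p = 0.0216 and 0.0202), with their calls lost in 4 and 2 of the 12 fits with 1 library left out (highest adjusted p 0.0543 and 0.0518). The member that rose was Cyp1a2, by 0.67 ± 0.11 (adjusted p = 0.00182).

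Acute phase genes, which hepatocytes induce in inflammation, had 27 measured members, of which 8 rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.51, or 0.26 without GH replicate 6 (camera adjusted p = 7.81e-10; adjusted p = 0.129 with an estimated correlation). Apcs, which encodes serum amyloid P, rose from 102 ± 23.1 to 284 ± 58.7 CPM (SD, n = 6; adjusted p = 0.000117). Orm1 rose by 0.79 ± 0.10 and Saa4 by 1.42 ± 0.18. Serpina3m rose by 0.78, but it overlaps Serpina3k on the same strand and lay just above it in CPM in all 12 libraries. The values were 11982 against 11337 CPM in PBS replicate 1 and 27612 against 27044 in GH replicate 1. Its counts thus look largely shared with Serpina3k, and its call among the 8 is not separate evidence. The member that fell was Orm3 (-1.39, adjusted p = 0.0146). Of 32 measured interferon response genes none rose and 4 fell in edgeR (0 and 4 adjusted over the list alone), with a median of -0.15, or -0.07 without PBS replicate 4 and -0.10 without GH replicate 2 (camera adjusted p = 2.3e-05; adjusted p = 0.200 with an estimated correlation). Those were the guanylate-binding protein genes Gbp7 (-1.01 ± 0.09, adjusted p = 1.23e-05) and Gbp3 (-0.52), and the immunity-related GTPase genes Igtp (-1.23 ± 0.13, overlapping Irgm2) and Iigp1 (-0.82). The calls of Gbp3 and Iigp1 were lost in 9 and 1 of the 12 fits with 1 library left out (highest adjusted p 0.0993 and 0.0541).

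Of 20 measured immediate-early and heat shock genes none rose and 2 fell in edgeR (0 and 2 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 0.000363; adjusted p = 0.0614 with an estimated correlation). They were the stress-induced genes Gadd45b (-1.84 ± 0.42) and Atf3 (-1.46 ± 0.40), which lost their calls in 1 and 9 of the 12 fits with 1 library left out (highest adjusted p 0.0506 and 0.110). Of 23 measured genes of endoplasmic reticulum (ER) stress and the integrated stress response 1 rose and 6 fell (2 and 8 adjusted over the list alone), with a median of -0.09 (camera adjusted p = 0.0091; adjusted p = 0.468 with an estimated correlation). Without GH replicate 6 that median was -0.04 (adjusted p = 0.0639), without PBS replicate 5 also -0.04, and without PBS replicate 2 or GH replicate 5 it was -0.05. The ER chaperone genes Hspa5 and Dnajb9 changed by -0.66 ± 0.15 and -1.06 ± 0.18, the transcription factor gene Atf4 by -0.50 ± 0.10 and Edem1, of ER-associated degradation, by -0.32. The gene that rose was Sdf2l1 (0.57, adjusted p = 0.0279), a call lost in 8 of the 12 fits (highest adjusted p 0.0676).

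**Figure D3:**
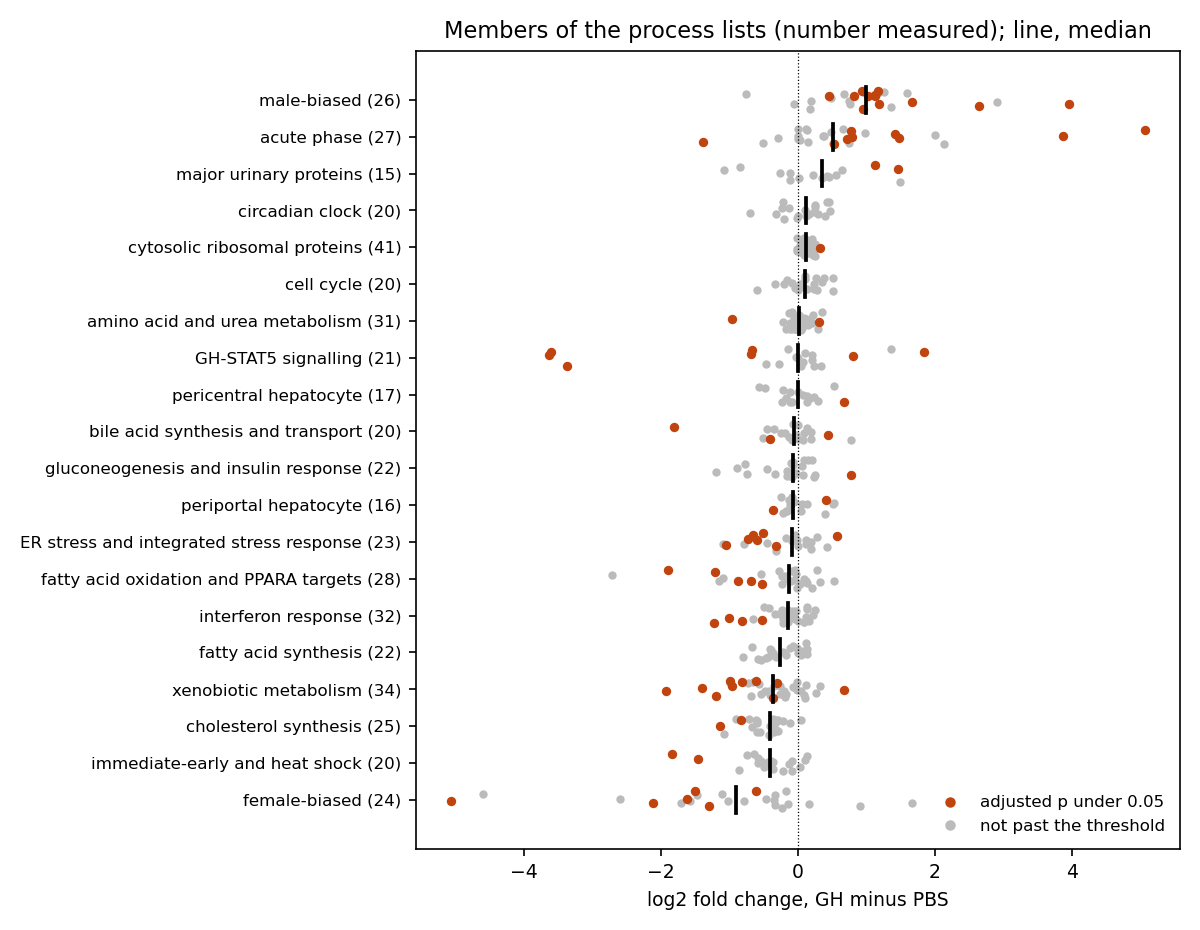
Log2 fold changes (GH minus PBS) of the measured members of the 20 process lists. Points are genes, coloured where the adjusted p is under 0.05, lines are list medians, and numbers in brackets are measured members. Medians ran from -0.90 for female-biased to 0.99 for male-biased genes.

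The remaining process lists held few changed genes. None of 20 circadian clock genes passed in edgeR or over the list alone (median 0.12; camera adjusted p = 0.121, or 0.0492 with a median of 0.22 without PBS replicate 1), and the smallest p belonged to Rora, which had a log2 fold change of 0.25 (adjusted p = 0.0828; DESeq2 gave 0.0434). Nor did any of 20 measured cell cycle genes (0 adjusted over the list alone; median 0.10, from -0.02 without PBS replicate 2 to 0.17 without PBS replicate 4; camera adjusted p = 0.382), where Mcm4 had 0.26 (adjusted p = 0.293). Of 22 genes of gluconeogenesis and insulin response 1 rose (1 adjusted over the list alone), Ppp1r3c, a glycogen-targeting subunit, by 0.77 ± 0.17 (SE, n = 6; adjusted p = 0.0177), with a list median of -0.07, or -0.02 without PBS replicate 5 (camera adjusted p = 0.775). Igfbp1, an insulin-repressed gene of the same list, had 227 ± 104 CPM in PBS and 98.7 ± 45.5 in GH (adjusted p = 0.122; 0.0289 in DESeq2). Of 31 amino acid and urea metabolism genes Ftcd rose by 0.31 and Mat1a, S-adenosylmethionine synthetase, changed by -0.96 (2 and 1 adjusted over the list alone). The list median was 0.01, from -0.02 without GH replicate 6 to 0.05 without PBS replicate 5 (camera adjusted p = 0.666). The calls of Ftcd and Mat1a were lost in 4 and 11 of the 12 fits with 1 library left out (highest adjusted p 0.0589 and 0.102). That of Mat1a was kept only without GH replicate 6, which had 4087 CPM. GH replicates 1 to 5 had 1367 to 1752 CPM of Mat1a and the PBS libraries 3072 to 4563. Ribosomal protein genes had a median of 0.12 over 41 members, or 0.07 without PBS replicate 2 and 0.19 without PBS replicate 5 (camera adjusted p = 3.86e-05; adjusted p = 0.611 with an estimated correlation). Neither fry (adjusted p = 0.202) nor the exact test of list means (adjusted p = 0.213) passed. Their only called member was Rplp0, at 0.33 (adjusted p = 0.0445; none adjusted over the list alone), with the call lost in 10 of 12 such fits (highest adjusted p 0.113).

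Markers of the liver lobule did not pass the list tests of movement one way. Fry's mixed test of change in either direction passed for both lists (adjusted p = 0.0105 each). Of 17 pericentral genes 1 rose, Cyp1a2 (1 adjusted over the list alone), with a median of -0.01, a mean of 0.01 and an upward direction in the camera test (adjusted p = 0.355). That median ran from -0.05 without GH replicate 1 to 0.08 without PBS replicate 2. Of 16 periportal genes Cyp2f2 rose by 0.40 and Ctsc changed by -0.37, a call lost in 6 of 12 fits with 1 library left out (highest adjusted p 0.0675). Their list had a median of -0.07, a mean of 0.03 and a downward direction in the camera test (adjusted p = 0.861), with 1 and 2 members adjusted over the list alone. The periportal median ran from -0.12 without PBS replicate 4 to 0.10 without PBS replicate 5.

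Markers of other cells showed few differences. None of 12 Kupffer cell and macrophage markers passed in edgeR or over the list alone (median -0.13; camera adjusted p = 0.231). Without PBS replicate 2 the Kupffer cell and macrophage median was -0.21 and passed (adjusted p = 0.0103), and without GH replicate 3 it was -0.07. Of 12 sinusoidal endothelium markers Tie1 rose by 0.28 (adjusted p = 0.0430; 3 adjusted over the list alone, with Stab1 and Stab2), with the call lost in 10 of 12 fits with 1 library left out (highest adjusted p 0.0998; list median 0.10, camera adjusted p = 0.231, or 0.0465 without PBS replicate 2). The matrix gene Dcn was the 1 of 12 stellate cell and fibroblast markers to change (-0.38 ± 0.06, adjusted p = 0.00296; 1 adjusted over the list alone; list median -0.04, from -0.11 without GH replicate 6 to 0.00 without GH replicate 3; camera adjusted p = 0.550). None of 7 cholangiocyte markers passed in edgeR (median 0.07, or 0.42 without PBS replicate 6; camera adjusted p = 0.604), with Sox9 higher when p was adjusted over the list alone. Sox9 passed over all genes without GH replicate 3 (adjusted p = 0.0343) and in DESeq2 (0.0453). The erythroid list had a median of 0.54 over 5 genes (camera adjusted p = 0.0261; adjusted p = 0.663 with an estimated correlation), but the call was lost in 4 of 12 such fits (highest adjusted p 0.122, without GH replicate 5). Without 1 library the median ran from 0.29 (GH replicate 5) to 1.32 (PBS replicate 5), with 0.33 without GH replicate 6 and 0.35 without PBS replicate 2. Their only called member was Alas2 (1 adjusted over the list alone), the erythroid form of the enzyme that starts haem synthesis, from 77.6 ± 21.5 to 171 ± 21.6 CPM (adjusted p = 0.00302). Its values did not follow those of the globin gene Hba-a1. GH replicates 2 and 4 had 184 and 159 CPM of Alas2 with 11.4 and 10.5 of Hba-a1, while PBS replicate 5 had 96.9 with 65.1. The rise of Alas2 alone is thus not a measure of erythroid cells.

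No member of the B cell (3 measured), T and NK cell (3) or neutrophil (2) lists passed in edgeR or over the list alone, with camera adjusted p of 0.604, 0.707 and 0.665. The medians were 0.02, 0.07 and 0.24. With 1 library left out they ran from -0.20 (GH replicate 3) to 0.17 (PBS replicate 4), from -0.28 (PBS replicate 3) to 0.17 (GH replicate 4) and from 0.05 (GH replicate 4) to 0.48 (PBS replicate 6). The B cell mean was -0.16 with a downward direction in the camera test, and Cd74 had a log2 fold change of -0.54 (adjusted p = 0.215). The pancreas list had 1 measured gene, which did not pass, and the adipose tissue and muscle lists had 0.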

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

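These tests were chosen after the main results were seen: the library and group swaps, the correlation with inflammation, the immune markers, the endotoxin genes, and the placing and depth of GH replicate 6. The fit of the acute phase list without GH replicate 6 was planned, and its use to weigh an explanation, with the estimated correlation in that fit, was chosen after. Across 272 groups of 6 values (the genes named, list means, the sex index and depth), 29 had a sample far from the others, where chance gives about 13.6, and 15 of the 29 were in GH replicate 6.

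The genes that GH is known to induce, Socs2, Cish, Igf1 and Igfals, were lower in the libraries labelled GH. For a swap of single libraries, 0 libraries lay inside the other group's range of Socs2, but this gene was already known to separate the groups. At genes of at least 2-fold called without the library placed, PBS libraries lay nearer to the PBS mean in 65.4% to 94.9% and GH libraries in 3.2% to 42.0%. This argues against such a swap, least clearly for GH replicate 6. A swap of the groups as a whole cannot be told apart from a response to GH, as no value in the table is tied to the hormone except through its response (Socs2 log2 fold change -3.38), and it would turn every direction in the report. Other genes tied to GH moved both ways, with log2 fold changes of 0.80 for Serpina3k, 1.84 for Serpina3c, -3.61 for Onecut1 and 1.36 for Bcl6 (adjusted p = 0.151). The male-biased and female-biased lists had medians of 0.99 and -0.90. All these values are responses as well, so they do not settle which group received GH. Livers were taken only at ZT 2, so the course of Socs2, Cish, Igf1 and Igfals after an injection was not measured. Inflammation, which may lower these genes, also stays open: within groups their mean and the acute phase mean had a Pearson r of -0.27 over 12 libraries (exact permutation p = 0.355; Spearman rho -0.34, exact p = 0.317), and r was 0.08 without GH replicates 6 and 3.

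Acute phase genes were higher in GH, which could reflect immune cells in the tissue, an endotoxin response to a contaminated injection, or 1 inflamed sample. Immune markers did not rise as a set, with a median log2 fold change of -0.09 over 20 genes (95% interval -0.24 to 0.02). This argues against the first for macrophages, which gave 12 of the markers. Other immune cells had few markers (2 for neutrophils), so little can be said of them. Genes of an endotoxin response still under way at sampling did not rise either, with a median of -0.16 over 20 genes (95% interval -0.27 to 0.05). Of these 0 were higher and 1 lower, Cxcl9 (-0.91, adjusted p = 0.0312, lost in 8 of 12 fits with 1 library left out). These values argue against such a response. An earlier one that had ended stays open, since no other time was sampled. Both intervals come from resampling the genes and leave out the spread between samples. Without GH replicate 6 the median fell from 0.51 to 0.26 (adjusted p = 4.91e-10; adjusted p = 0.0664 with an estimated correlation), but 9 members were called higher and 1 lower, so it is not the whole cause. A direct response to GH was not separated from these.

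The sex index of GH replicate 6 was 4.581, against 6.25 to 6.52 in the other GH libraries. Its male-biased mean of 7.309 and female-biased mean of 2.728 (log2 CPM) stood apart from the rest of the group as well. At genes of at least 2-fold called without it, GH replicate 6 lay nearer to the PBS mean in 42.0% (exact 95% interval 33.7 to 50.7). PBS libraries placed the same way gave 65.4% to 94.9% and other GH libraries 3.2% to 14.2%. The interval counts genes as independent and leaves out the spread between samples, so it is likely too narrow. Since the share itself lay outside both ranges, it argues only weakly against a mislabelled PBS library. Shallow sequencing is excluded by its total of 23.07 M counts (M, mega). A weaker or different response in this sample, or fewer doses received, was not tested.

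Other values far from their group in GH replicate 6 were 1.846 CPM of Socs2, 3125 of Saa2, 3056 of Saa1, 23.21 of Gstt3, 362.8 of Sult1a1, 4087 of Mat1a, 83.99 of Por, 417 of C6, 6.9 of Cxcl9, 124 of Stab2 and 50.59 of Nr1h4. The 1 measured gene of the pancreas list had a log2 CPM of 3.189 there.

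In other GH libraries, GH replicate 2 had 0.7481 CPM of Acot2 and 611.9 of Egfr. GH replicate 5 had 238.7 CPM of Creb3l3, a mean log2 CPM of 4.752 over the GH and STAT5 signalling genes and of 0.6566 over the T and NK cell markers. The Kupffer cell and macrophage mean of GH replicate 3 was 3.996, and the neutrophil mean of GH replicate 1 was -1.885.

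Among PBS libraries, PBS replicate 6 had 319.7 CPM of Ehhadh, 50.52 of Cyp2c40 and a neutrophil mean log2 CPM of 0.6552. Apcs had 148.8 CPM in PBS replicate 4. PBS replicate 2 had 4.177 CPM of Gadd45b and 2.675 of Sox9, and the periportal mean of PBS replicate 5 was 8.978.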

How the results depend on the processing

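Leaving out GH replicate 6 and PBS replicate 5 together was chosen after seeing the data. No result that passed its threshold was reversed in any alternative. The 682 changed genes were 1057 with DESeq2 (506 higher, 551 lower; 681 shared), where test, filter (14668 genes) and scaling differed together and the cause was not tested. They were 226 at an adjusted p under 0.01, 1124 under 0.1 and 129 when the fold was tested against 1.2, differences that follow from the threshold. Scaling by library size alone gave 211 higher and 658 lower genes, 1 surrogate variable 495 higher, and leaving out GH replicate 6 and PBS replicate 5 518 higher. The cause was not tested. Limma-voom, other factors, other filters and non-robust estimation gave 642 to 683 changed genes. The surrogate variable was positive only in PBS replicates 1 and 2 and GH replicates 5 and 6. Those libraries had circadian clock means of 4.08 to 4.29 (log2 CPM), against 3.31 to 3.80 in the other libraries. With 1 library left out the counts were 434 to 854 changed, 193 to 410 higher and 241 to 444 lower.

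The male-biased and female-biased lists passed camera in every fit of these alternatives (medians 0.92 to 1.11 and -1.49 to -0.70 with 1 library left out). They did not pass camera with an estimated correlation (adjusted p = 0.0614 and 0.129), where correlated members carry less information. Fry's test of movement one way passed for both (adjusted p = 0.00302 and 0.0172). The sex index difference was 1.93 to 2.73 with 1 library left out, and the median of the GH-STAT5 signalling list -0.0435 to 0.0335, passing camera once, without PBS replicate 6 (adjusted p = 0.0446). Replicate numbers did not pair the samples: correlations of same-numbered libraries were -0.03, -0.11, 0.15, 0.16, -0.17 and -0.18, and 2 of the 12 libraries correlated best with their own number. With the number as a replicate block 391 genes were called, 180 higher and 211 lower. Counts of 19523104 to 23278931 per library and 6 samples per group limit the detection of small changes: 50.7% of genes changed 1.5-fold were recovered in simulated data.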

Other observations

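The complement and coagulation test was chosen after its leading genes had been seen, and the count of splits was planned. The genes of this paragraph were picked after their values were seen, and no list of the terminal complement pathway was tested. C9 rose by 0.83 ± 0.13 and Hc, which encodes component C5, by 0.64 ± 0.09 on the log2 scale (SE, n = 6; adjusted p = 0.00165 and 0.000924). F11, coagulation factor XI, rose by 0.74 ± 0.07 (adjusted p = 2.23e-05). Of the lectin pathway genes Masp1 and Masp2 rose by 0.30 and 0.27, while Mbl2 changed by -0.68 ± 0.10 (adjusted p = 0.00137).

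A candidate explanation for the small p of F11 and Hc is that liver genes of complement and coagulation rose as a group. Over the other 30 measured genes of such a list the median log2 fold change was 0.16, with 9 higher and 1 lower (camera p = 3.76e-05; p = 0.00964 with an estimated correlation; fry p = 5.36e-06). The list was written after F11 and Hc were seen, so this is a hypothesis that may also reflect the acute phase, and it was not tested on other samples.

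Of 100 splits of the 12 libraries into 6 and 6, drawn from 462, 1 gave as many changed genes as the groups, namely the real split with 682, and the highest of the others gave 14. A random division of the libraries is thus an unlikely source of that count, though 100 splits cannot show a share below 1 in 100. They also cannot tell GH from any other difference that follows the groups.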
